A study of Mus musculus with 6 samples.

How the data were processed

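RNA-seq libraries were made from whole testes of C57BL/6J mice at 12 days post-partum, 3 from wild-type and 3 from Ankrd31 knockout animals, with a strand-specific kit per the labels' protocols. The authors deposited 1 table of raw read counts per gene for the 6 libraries, with no normalization. Per the submitters' processing notes, bcl2fastq 2.19.1, GSNAP (release of 2018), featureCounts 1.6.0 and the genome build mm10 were used, and the layout of the header is that of featureCounts; strand setting, treatment of reads with several matches, annotation release and filters are not given in the sources used here. The length column holds the summed exon length of each gene in bases, per the file headers, and served for a length correction. Reads of near-identical genes, such as Zfy1 and Zfy2, may have been lost or split, which makes those counts uncertain.

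The table had 49763 rows, of which 92 were spike-in sequences with 1 count in all libraries together; these were left out. Of 49671 gene rows, 49412 identifiers matched GENCODE M21, which gave symbols, biotypes and chromosomes, and 259 with 0.0193% of counts did not; 91.5% of the matched genes had the same start and end in both. Samples were grouped by the genotype in the labels, and counts were joined to samples by the titles in the column names. Totals were 21014060 to 22706296 counts. The chi-square per degree of freedom between replicates of a group was 7.35 to 12.96 over genes with at least 10 counts, so no library was a duplicate of another of its group. The design text names 3 mice per genotype, and the labels do not say whether numbers mark litters or days.

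Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood fit, two-sided F test), with Benjamini-Hochberg adjustment over the 18040 tested genes and a threshold of 0.05. Group values are means and SD of CPM over 3 libraries, and log2 fold changes are knockout over wild type with SE, the median SE being 0.113 and the biological coefficient of variation 10.2% (0.085 and 5.67% with the block). The groups share replicate numbers 1 to 3. Deviations from the group means correlated at 0.42, 0.26 and 0.28 between libraries of the same number, each over the limit of 0.1 set for pairing, and at -0.29 to 0.02 between libraries of different numbers. Deviations within a group cancel out, so the second range is not separate evidence, and these correlations were not tested against chance. The numbers were taken to pair the samples on this hint from the same data. The fit with the replicate number as a block is given beside a result where it changes the call. The unblocked fit was the primary one.

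Before the data were examined, 28 gene lists covering meiosis, germ cell stages, somatic cells of the testis, epididymis, stress and sex chromosomes, and 22 chromosome sets were fixed, and the 50 sets were tested as one family with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, at least 5 tested members). Camera with an estimated correlation and fry, which tests whether a set moves on balance in one direction, were run beside it. The named genes were Ankrd31, up to 15 passing genes per direction (5 with the smallest p where fewer than 5 passed), and the 4 members of each list with the smallest p; the text gives a selection of the last, and the genes called with the block, Tex16, Tsx, Hsd3b1, Spo11, Dmc1, Gm42418, Crisp1 and the genes of lists added later were named after their values were seen. Some results are not reported here. DESeq2 1.42.0 and limma voom, other normalizations and filters, covariates, and fits without each library were alternatives. GC and length corrections used a loess trend per library (span 0.5) as offsets, with GC known for 99.8% of tested genes. Fits without a whole pair, these corrections and the axis-list covariate were added after the data were seen, as were the sex-linked shares of genes and their Fisher tests.

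The tests were run on simulated counts for 18040 genes in the comparison of knockout and wild type, with 67, 67 and 66 genes changed by 1.5, 2 and 4 fold. Without the block edgeR recovered 64.2%, 77.6% and 97.0% of them, with 14 false calls (8.1% of all calls); with the block it recovered 67.2%, 92.5% and 100%, with 28 false calls (13.9% of all calls, above the nominal level). A simulated list shifted by 0.3 on the log2 scale passed camera with an estimated correlation without the block (adjusted p = 0.0251) and not with it (0.259). The simulated genes were drawn independently of each other. The real lists that passed had estimated correlations of 0.114 to 0.768 and smaller mean changes, so the simulation does not measure the power of that test on them.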

Results

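Whole testes of juvenile C57BL/6J mice were profiled by RNA-seq at 12 days post-partum, an age at which the first wave of germ cells is entering and passing through early meiotic prophase. The design set 3 mice with a homozygous loss of Ankrd31 against 3 wild-type mice. Ankrd31 encodes an ankyrin-repeat protein that acts with the machinery making the programmed DNA double-strand breaks of meiosis. The libraries held 21945226, 22706296 and 21014060 counts assigned to genes in wild-type replicates 1, 2 and 3, and 21972002, 22055492 and 22415062 in knockout replicates 1, 2 and 3. After removal of genes with low counts, 18040 genes were tested. The first principal component took 36.7% of the variance and placed replicate 1 of both genotypes together, at -25.55 and -23.37, with the other libraries between 3.75 and 22.84. The third took 14.1% and parted the genotypes, with wild-type libraries between 3.16 and 14.83 and knockout libraries between -17.06 and -0.59.

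Ankrd31 (ENSMUSG00000109561, mm10 chromosome 13, 96748272 to 96910039, plus strand) was lower in each knockout library than in every wild-type library. Its level was 84.94, 52.29 and 63.25 CPM (counts scaled to the effective library size) in the wild-type replicates and 40.84, 33.15 and 38.02 CPM in the knockout replicates. The means were 66.8 ± 16.6 and 37.3 ± 3.89 CPM (SD, n = 3 each), so that the knockout stood at 55.9% of the wild-type level. The log2 fold change was -0.84 ± 0.17 (SE), and in edgeR's quasi-likelihood test the gene had an unadjusted p of 0.00154 and did not pass after Benjamini-Hochberg adjustment. With the replicate number as a block, the log2 fold change was -0.82 ± 0.07 and the gene passed in edgeR at an adjusted p of 0.00505. Over 29 alternatives it was lower in all 29 and passed in 10, with edgeR, DESeq2 or voom adjusted p-values from 6.48e-11 to 1. The counts cover the whole gene, so exons outside the deleted part contribute to them and the level checks the genotype labels only in part.

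Ankrd31 and the kinase-related gene Trib2 fell in the knockout testes, and 6 genes rose, when each knockout library was compared with the wild-type library of the same replicate number. The 6 were Rn7sk, which encodes a small nuclear RNA that restrains transcription elongation, the noncoding RNA gene Gm23935, the Y-linked zinc finger gene Zfy2, and the X-linked genes 1700080O16Rik, Pet2 and 1700013H16Rik. Zfy2 went from 4.59 ± 2.62 to 9.51 ± 3.55 CPM (SD, n = 3) and had a blocked log2 fold change of 1.10 ± 0.14 (SE, edgeR adjusted p = 0.0109). The gene 1700080O16Rik went from 3.92 ± 1.40 to 8.758 ± 4.004 CPM, with 1.14 ± 0.14 (edgeR adjusted p = 0.00963). Pet2 went from 48.4 ± 17.4 to 69.0 ± 16.4 CPM, with 0.54 ± 0.07 (edgeR adjusted p = 0.0108). Rn7sk went from 13.97 ± 1.27 to 24.01 ± 4.84 CPM, with 0.77 ± 0.09 (edgeR adjusted p = 0.00869). Gm23935 had 0.33 ± 0.05 (0.0295), 1700013H16Rik 0.35 ± 0.05 (0.0323) and Trib2 -0.34 ± 0.05 (0.0323), with the blocked edgeR adjusted p in brackets. Each of these 8 genes moved in the same direction in 3 of 3 pairs (figure of levels in each library). The genes were picked by the blocked fit on these same pairs, so this agreement follows largely from the choice and is no separate support. Rn7sk is a structured small RNA, a group for which carry-over of ribosomal RNA could not be told apart from genotype. The log2 ratios of Gm23935 were 0.417, 0.229 and 0.333 in pairs 1, 2 and 3. They ranked as those of Gm42418, which overlaps ribosomal RNA (0.776, -0.033 and 0.428), and carry-over was not tested for Gm23935. With the block, limma voom called Ankrd31 alone of the 8 (its adjusted p was 0.053 to 0.114 for the other 7). With the block and a GC correction, Trib2 and 1700013H16Rik did not pass in edgeR (adjusted p = 0.0583 and 0.0777). Without the block Zfy2 had 1.05 ± 0.45, 1700080O16Rik 1.16 ± 0.38 and Pet2 0.51 ± 0.31. Zfy1, a near-identical copy of Zfy2, had a blocked log2 fold change of 0.79 ± 0.14 and did not pass in edgeR (adjusted p = 0.0775), and reads shared between the copies make both values uncertain. Without the block, edgeR called 0 of 18040 genes, with 374 at an unadjusted p under 0.05 where chance alone would give 902; DESeq2 called 2 (Ankrd31 and Rn7sk; 242 unadjusted) and limma voom 0 (382 unadjusted). The blocked count was 0 without pair 3, 63 without pair 1 and 57 without pair 2, and 5 of the 63 and 8 of the 57 were among the 8 genes above. The 57 included epididymis and rete genes that were high in wild-type replicate 3, such as Crisp1 (-3.36) and Cdh16 (-3.69). They also included Gm42418 (0.602) and the mitochondrial ribosomal RNAs mt-Rnr1 (0.497) and mt-Rnr2 (0.489). The larger counts therefore cannot be read as more effects of genotype. Of the sex-linked genes, Pet2 had its lowest unblocked value without wild-type replicate 2 (0.30), and Zfy2 and 1700080O16Rik without knockout replicate 1 (0.73 each).

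The genes with the smallest unadjusted p without the block, none of which passed in edgeR, included several noncoding RNAs on the higher side and signalling genes on the lower side. Gm22513 had a log2 fold change of 2.23 ± 0.35 from 0.334 to 1.59 CPM, Rmrp, the RNA component of the mitochondrial RNA processing endoribonuclease, 0.93 ± 0.20, and the mitochondrial ribosomal RNA mt-Rnr1 0.40 ± 0.09. Gm14599 on the X chromosome had 1.83 ± 0.42 at 0.214 and 0.773 CPM. On the lower side, the Wnt receptor gene Fzd2 had -0.36 ± 0.09, the Notch target Heyl -0.41 ± 0.11 and Ankrd63 -1.18 ± 0.31.

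**Figure D1:**
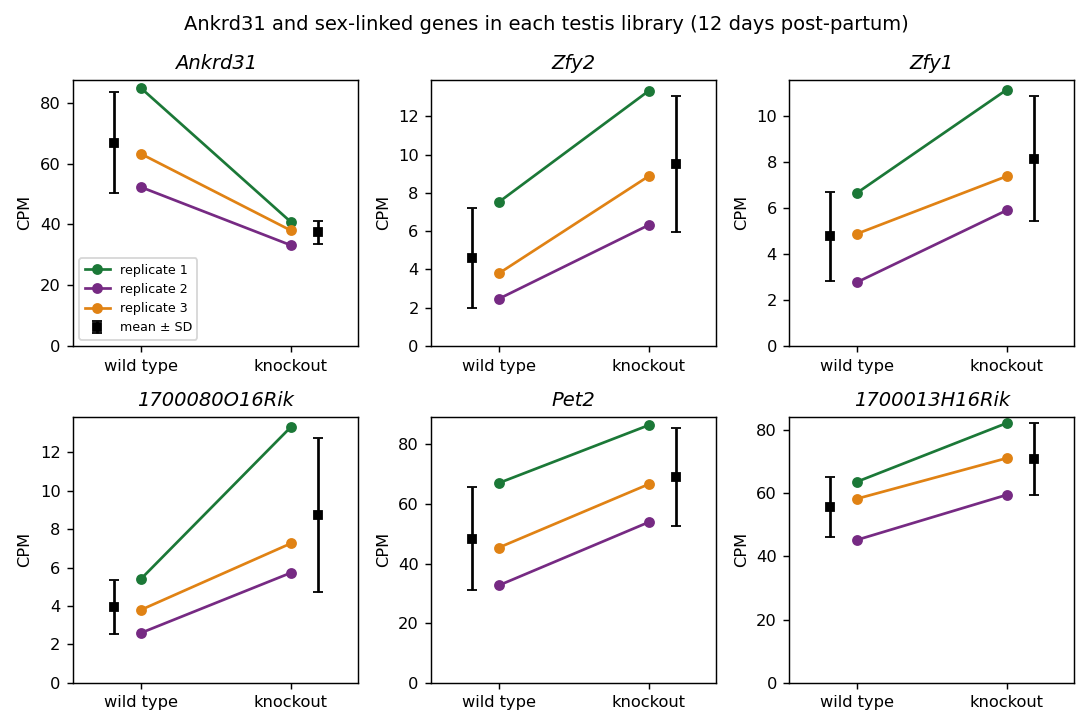
Level in CPM of Ankrd31 and of 5 sex-linked genes in each library; coloured lines join the wild-type and knockout libraries of the same replicate number, and black squares give the group mean ± SD (n = 3). Ankrd31 lies between 33.15 and 40.84 CPM in the knockout libraries and between 52.29 and 84.94 CPM in the wild-type ones, while each of the other genes is higher in the knockout library of all 3 pairs. Apart from Zfy1, these genes were picked by the blocked fit on the same pairs, so their agreement over pairs is no separate support.

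Genes on the sex chromosomes were over-represented among those higher in the knockout testes (figure of shares by chromosome). Of the 6 genes that rose with the block, 4 lie on the X or Y chromosome, against 891 of 18040 tested genes (4.94%). This count prompted the tests of shares below, which were chosen after it was seen and run on the same libraries. At an unadjusted p under 0.05 in the blocked fit, 86 of 648 higher genes (13.3%) were sex-linked, 82 on X and 4 on Y (odds ratio 3.15, Fisher's exact test, two-sided, p = 3.38e-17), while 30 of 701 lower genes (4.28%) were (p = 0.476). Without the block the share was 19 of 152 higher genes (12.5%, Fisher's exact p = 0.000182). In the blocked fit the share was 9.39%, 14.8% and 15.6% of the higher genes when pair 1, 2 or 3 was left out, and 12.6% after a correction for GC content. Genes are not independent replicates, so these p-values describe the gene sets in these libraries.

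**Figure D2:**
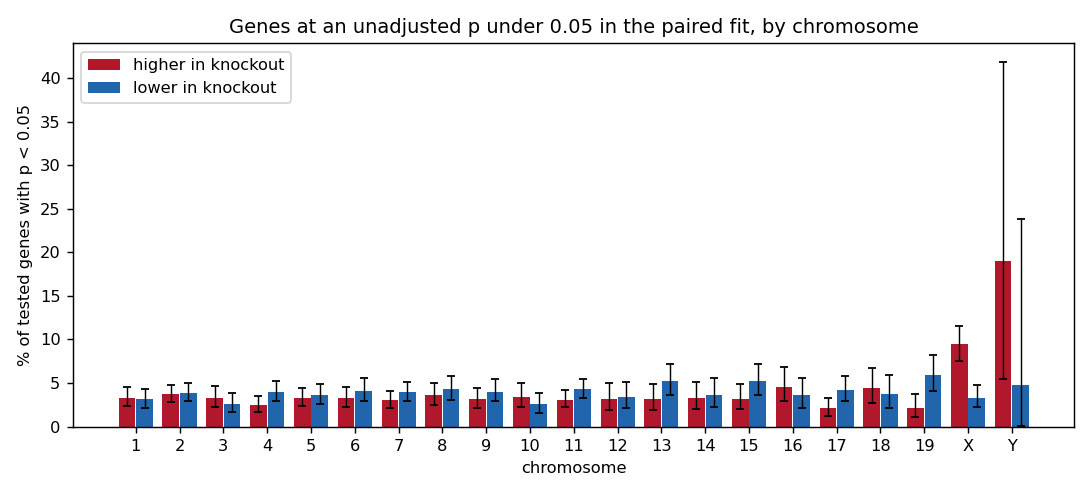
Percentage of the tested genes of each chromosome that were higher (red) or lower (blue) in the knockout libraries at an unadjusted p under 0.05 in edgeR with the replicate number as a block; bars start at 0 and lines are exact 95% binomial intervals, which cover counting of genes only. On the X chromosome 9.43% of genes were higher and 3.33% lower, and on the Y chromosome, with 21 tested genes, 19% and 4.76%.

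The list of X-linked genes expressed in germ cells and the list of Y-linked genes were higher in the knockout testes in limma's camera test with a preset correlation. Under that test 8 lists passed, and 7 of the 10 splits of the 6 libraries into 3 against 3, the real one included, gave at least 8. The highest other count was 16. The number of passing lists, here and below, thus does not set the genotypes apart from other groupings of the libraries. Of 20 X-linked members, 16 were higher, with a mean log2 fold change of 0.09 (camera adjusted p = 0.00177), and of 9 Y-linked members 8 were higher, with a mean of 0.28 (camera adjusted p = 0.0105). Both calls were lost with an estimated correlation (camera adjusted p = 0.841 for each). The Y-linked median was 0.14, and the near-identical Zfy1 and Zfy2, whose counts are uncertain, had 0.77 and 1.05 without the block. Adjusted over the list alone in the blocked edgeR fit, 4 X-linked members rose, namely 1700013H16Rik, the ubiquitin protease gene Usp26 (0.16 ± 0.05), Tex16 and the TFIID subunit gene Taf7l (0.16 ± 0.04), and 4 Y-linked members rose, namely Zfy1, Zfy2, Usp9y (0.24 ± 0.06) and Eif2s3y (0.14 ± 0.05). Without the block 0 members of either list did. Neither list passed without wild-type replicate 2 (means 0.05 and 0.17) or knockout replicate 1 (0.08 and 0.20), or with a GC correction without the block (0.05 and 0.23; both passed with the correction and the block), and the Y-linked list did not pass without knockout replicate 3 (0.29). The X-linked mean was 0.14 without wild-type replicate 1 and without knockout replicate 2.

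Genes of early meiotic prophase were also higher as groups under the preset correlation, under which other splits of the libraries gave as many passing lists. The calls of the 3 lists below were lost with an estimated correlation (camera adjusted p = 0.841 for each). Double-strand break formation genes had a mean log2 fold change of 0.16, with 13 of 14 members higher (camera adjusted p = 0.00177), and chromosome axis and synaptonemal complex genes 0.13, with 23 of 24 higher (camera adjusted p = 0.003). Recombination and repair genes had 0.10, with 31 of 41 higher (camera adjusted p = 0.0121). Mei4, a partner of the break machinery, had 0.30 ± 0.12, the chromatin remodeller Hells 0.14 ± 0.07 and the cohesin gene Smc1b 0.15 ± 0.12. The synaptonemal complex gene Syce2 had 0.11 ± 0.10, the helicase gene Brip1 0.18 ± 0.09 and the histone variant gene H2afx -0.22 ± 0.09, and none of these passed in edgeR over all genes. Adjusted over the list alone, 0 members passed without the block; with it, Spo11, whose product makes the breaks, and Hells rose (0.44 ± 0.13 and 0.14 ± 0.04), and of the recombination list the strand exchange gene Dmc1 rose (0.26 ± 0.05) and H2afx fell (-0.22 ± 0.05). In pair 1 the mean log2 ratios of these lists were 0.01, -0.01 and -0.04, against 0.26, 0.25 and 0.20 in pair 2 and 0.20, 0.14 and 0.13 in pair 3. Without wild-type replicate 2 the means were 0.02, -0.03 and -0.02 and no list of the 3 passed, nor did any without knockout replicate 1 (0.09, 0.02 and 0.03). Without wild-type replicate 1 they were 0.30, 0.31 and 0.23, and without knockout replicate 2 0.25, 0.23 and 0.17. The axis and recombination lists did not pass without wild-type replicate 3 (0.12 and 0.09) or with a GC correction without the block (0.10 and 0.08; with the block both passed), nor the recombination list without knockout replicate 3 (0.10).

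Genes of the cholesterol synthesis list were lower in the knockout testes in the preset camera test, with 22 of 22 members lower and a mean log2 fold change of -0.17 (camera adjusted p = 4.53e-10). The call was lost with an estimated correlation (camera adjusted p = 0.841). The feedback regulator gene Insig1 had -0.24 ± 0.08, the squalene epoxidase gene Sqle -0.20 ± 0.08 and Mvk -0.31 ± 0.12; 0 members passed in edgeR over all genes or adjusted over the list alone. Of all leave-outs of 1 library, that of wild-type replicate 3 gave the smallest change (-0.09). The mean log2 ratio was -0.01 in pair 1, -0.08 in pair 2 and -0.42 in pair 3, where the epididymis and rete list stood at -1.22 and the Leydig list at -0.64. Without pair 3 the blocked mean was -0.05 and the list did not pass (camera adjusted p = 0.283).

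Among genes of other testis cells (figure of gene lists in each pair), endothelial genes were lower in the preset camera test (mean log2 fold change -0.11, 12 of 15 members lower, camera adjusted p = 0.0105). The call was lost with an estimated correlation (camera adjusted p = 0.841). Sox17 stood at -0.46 ± 0.15 and the VEGF receptor gene Kdr at -0.31 ± 0.15. Adjusted over the list alone, Kdr fell with the block and 0 members passed without it. The list did not pass without wild-type replicate 3 (-0.05) or knockout replicate 1 (-0.07), without pair 3 or with a GC correction and the block (-0.08 each), and stood at -0.18 without wild-type replicate 1. Macrophage and other immune genes were higher (0.12, 17 of 20 members, camera adjusted p = 0.0267, and adjusted p = 0.841 with an estimated correlation), and their mean log2 ratio was 0.04 in pair 1, 0.61 in pair 2 and -0.29 in pair 3. The list did not pass without wild-type replicate 1 (0.14), wild-type replicate 2 (-0.04) or knockout replicate 2 (0.05), and had a mean of 0.28 without wild-type replicate 3. Leydig cell genes did not pass (camera adjusted p = 0.361), and their pair ratios ran from -0.64 in pair 3 to 0.62 in pair 2. Adjusted over the list alone in the blocked edgeR fit, the steroid synthesis genes Hsd17b3 (-0.55 ± 0.12) and Hsd3b1 (-0.22 ± 0.06) fell. Both were lower in 3 of 3 pairs, which follows largely from their choice by that fit. Star, which carries cholesterol into mitochondria for steroid synthesis, lay at 43.19, 37.47 and 24 CPM in the wild-type and 96.67, 187.73 and 22.98 CPM in the knockout replicates. Epididymis and rete genes did not pass (mean -0.36, camera adjusted p = 0.1), with a mean log2 ratio of -0.01 in pair 1, 0.15 in pair 2 and -1.22 in pair 3. In wild-type replicate 3, Cdh16 reached 11.5 CPM and Krt8 5.87 CPM against at most 0.95 and 0.68 CPM in the other libraries. Crisp1, an epididymal secretory protein gene below the count filter, had 628 counts in wild-type replicate 3, 64 in knockout replicate 3 and at most 3 in the others.

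**Figure D3:**
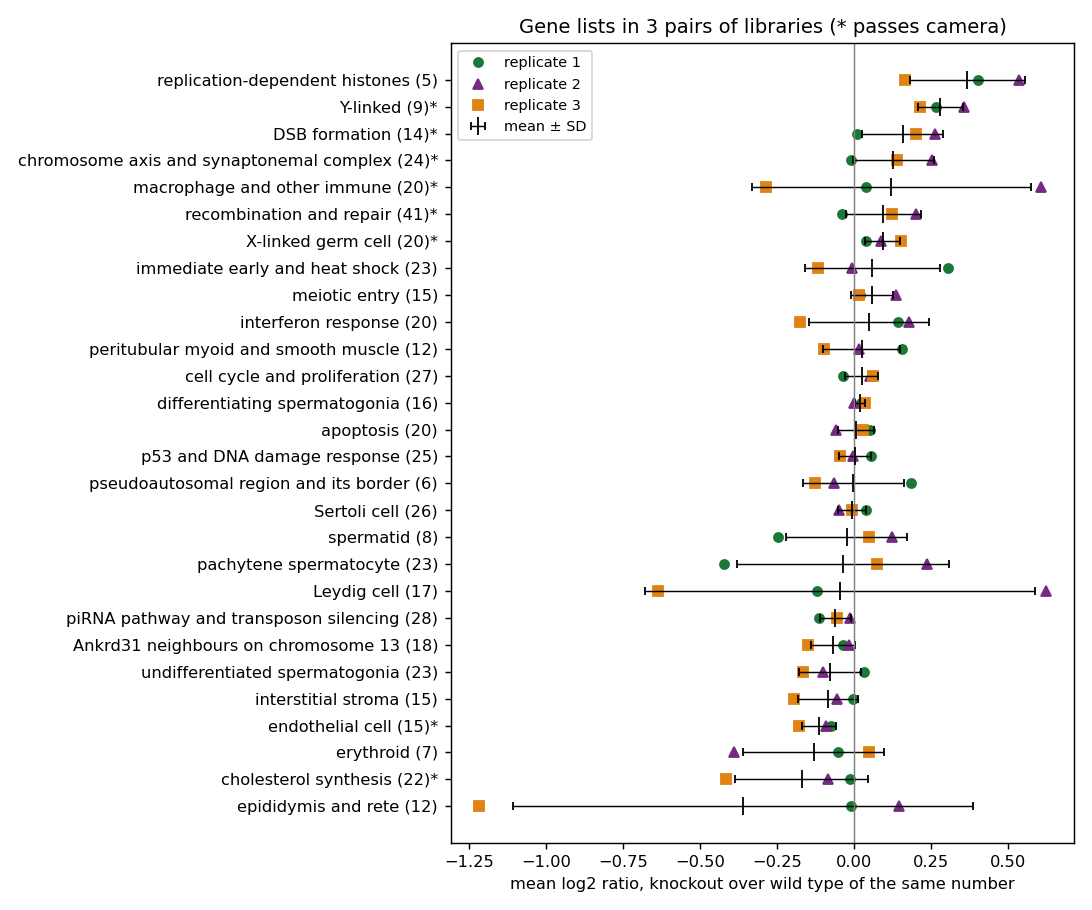
Mean log2 ratio, knockout over wild type, of each gene list in the 3 pairs of libraries that share a replicate number; coloured symbols are pairs, black lines the mean ± SD over the pairs, numbers in brackets the tested genes, and a star a list that passed camera with the preset correlation. The Y-linked list, which holds Zfy1 and Zfy2 with their larger and uncertain rises, lies between 0.213 and 0.358 in all pairs. The cholesterol synthesis list lies at -0.415 in pair 3 and between -0.084 and -0.012 in the other pairs.

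With the block, interstitial stroma genes were also lower (mean log2 fold change -0.08, camera adjusted p = 0.0263) and meiotic entry genes higher (0.06, camera adjusted p = 0.0263), where they did not pass without it (0.1 and 0.527). With an estimated correlation and the block, camera gave both an adjusted p of 0.663. In pairs 1, 2 and 3 the mean log2 ratios were -0.004, -0.054 and -0.193 for stroma, and 0.02, 0.137 and 0.018 for meiotic entry. Nr2f2, which encodes a transcription factor of stromal cells, fell in the blocked edgeR fit adjusted over the list alone (-0.19 ± 0.05), and Taf4b, a germ cell TFIID subunit gene of the meiotic entry list, had 0.17 ± 0.05 and did not pass. The other 16 germ cell, somatic and stress lists passed neither with nor without the block. Their mean log2 fold changes were -0.08 for undifferentiated spermatogonia, 0.02 for differentiating spermatogonia, -0.04 for pachytene spermatocytes, -0.02 for spermatids, -0.06 for the piRNA pathway, -0.01 for Sertoli cells, 0.02 for peritubular myoid cells and -0.13 for erythroid genes. They were 0.003 for the p53 and DNA damage response, 0.007 for apoptosis, 0.06 for immediate early and heat shock genes, 0.05 for the interferon response, 0.03 for the cell cycle, 0.37 for 5 replication-dependent histones, -0.002 for the pseudoautosomal region and its border, and -0.07 for genes next to Ankrd31. Among their members, Nanos3 of undifferentiated spermatogonia had -0.41 ± 0.16, the cyclin gene Ccnd2 -0.28 ± 0.14, the piRNA-binding gene Piwil1 -0.64 ± 0.37, Amh of Sertoli cells -0.30 ± 0.21, the proapoptotic gene Pmaip1 0.31 ± 0.17 and the pseudoautosomal gene Asmt 0.35 ± 0.19, none passing in edgeR over all genes. Adjusted over the list alone in the blocked edgeR fit, Ccnd2 (-0.27 ± 0.06), the Sertoli list's Wnt6 (-0.24 ± 0.06) and F2r near Ankrd31 (-0.34 ± 0.09) fell, and Hist1h2aa (1.26 ± 0.40) and the Sertoli list's Tsx (0.57 ± 0.13) rose.

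Of 22 chromosome sets, the X chromosome alone was higher as a whole in the preset camera test, with a mean log2 fold change of 0.04 over 870 genes (camera adjusted p = 0.0267). Its mean log2 ratio was 0.056 in pair 1, 0.059 in pair 2 and -0.006 in pair 3, so it was not higher in pair 3. The call was lost with an estimated correlation (camera adjusted p = 0.488) and after a GC correction (mean 0.02, camera adjusted p = 0.617, and 0.515 with the block). It was also lost without wild-type replicate 1 (0.04) or 2 (0.02) and without knockout replicate 1 (0.02), 2 (0.04) or 3 (0.05). The 21 tested Y-linked genes had a mean of 0.11 (camera adjusted p = 0.105). The 81 tested genes within 5 Mb of Ankrd31 on chromosome 13 did not pass (mean -0.02, camera adjusted p = 0.966).

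Mitochondrial transcripts made up 1.97 ± 0.0388% of counts in the knockout libraries and 1.67 ± 0.174% in the wild-type libraries (SD, n = 3 each, exact permutation p = 0.1, two-sided), higher in 3 of 3 pairs. Structured small RNAs made up 0.0238 ± 0.00339% and 0.0146 ± 0.00214% (exact permutation p = 0.1). The share of Gm42418, a gene that overlaps ribosomal RNA, was 0.945 ± 0.230% and 0.715 ± 0.0711% (exact permutation p = 0.3). With 3 libraries per group the smallest possible two-sided p is 0.1, so none of these shares could pass at 0.05.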

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

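The fits without a whole pair, the GC and length corrections, the axis-list covariate, the Leydig covariate on lists, and DESeq2, voom, estimated correlation and fry with the replicate block were tests chosen after the data were seen. Where edgeR without the block called 0 genes (374 at an unadjusted p under 0.05; DESeq2 2, voom 0), the count of genes was 1 without a filter, 8 with the replicate block, 1 with the pachytene covariate, 6 with GC correction and block, 8 with length correction and block, 1 with the axis covariate, 14 with DESeq2 and block, and 1 with voom and block. All 6 of the GC-corrected calls (without Trib2 and 1700013H16Rik), 8 of the 8 length-corrected and 8 of the 14 DESeq2 calls with the block were among the 8 blocked edgeR calls. Ankrd31 passed, where it did not in edgeR without the block, with DESeq2 (-0.84), the block (-0.82), the pachytene covariate (-0.79), GC correction and block (-0.85), length correction and block (-0.81), the axis covariate (-0.94), DESeq2 and block (-0.81) and voom and block (-0.83); it ranged from -0.99 without wild-type replicate 2 to -0.63 without wild-type replicate 1. The 8 lists became 0 with an estimated correlation, 0 with fry, 3 with a GC correction without the block, 5 with the axis covariate, and 0 with either an estimated correlation or fry and the block. The count of chromosome sets went from 1 to 0 with an estimated correlation, with fry, with a GC correction (with and without the block) and with an estimated correlation or fry and the block, and to 2 with the pachytene covariate. The replicate block changed no other call of a list or chromosome set than those of stroma and meiotic entry. Over fits without 1 library or 1 pair, counts ran from 0 to 63 genes (63 without pair 1; 0 without pair 3 and without each single library), from 2 lists without knockout replicate 1 to 13 without wild-type replicate 1, and from 0 to 2 chromosome sets (2 without pair 2). Values that changed sign in these fits ran from lowest to highest as follows, none of them passing in edgeR with all 6 libraries: Bok -0.37 to 0.044, Dmrtb1 -0.0015 to 0.15, Cdh16 -3.69 to 0.24, Krt18 -2.35 to 0.041, Krt8 -2.62 to 0.63, Hbb-bs -0.31 to 0.073, Bpgm -0.11 to 0.0035, Hba-a1 -0.30 to 0.12, Mrc1 -0.013 to 0.45, Prdm9 -0.045 to 0.32, Des -0.19 to 0.082, Myl9 -0.034 to 0.12, Arhgap6 -0.21 to 0.11 (0.036 with the axis covariate), Lrrc34 -0.78 to 0.016, Pou5f1 -0.56 to 0.0022 and Cdh1 -0.54 to 0.0045. Lists that changed sign were chromosome axis and synaptonemal complex (-0.030 to 0.31), macrophage (-0.12 to 0.33), pachytene spermatocyte (-0.25 to 0.28), recombination and repair (-0.019 to 0.23) and Sertoli cell (0.055 without wild-type replicate 2). The highest of Cdh16, Krt18, Krt8, Arhgap6 and Cdh1 came without wild-type replicate 3, and the lowest axis and recombination means without wild-type replicate 2; the causes were not tested. Over the named genes other than Ankrd31 and the alternatives, 3367 values kept direction and side of the threshold, 55 passed where the unblocked fit did not and 26 changed sign. As the unblocked edgeR fit called 0 genes, the 3367 values passed neither there nor in the alternative, and no call could be lost. The depth of 21014060 counts or more per library gave a median SE of the log2 fold change of 0.113 without and 0.085 with the block.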

Other observations

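The Notch, fatty acid, ribosomal protein, respiratory chain, mitochondrial and structured RNA lists, the sex-linked and early meiotic groupings, and the weighing tests below, except the splits of the libraries, were chosen after the results were seen. Notch pathway genes (-0.04, camera adjusted p = 0.409), fatty acid synthesis genes (-0.01, camera adjusted p = 0.57) and ribosomal protein genes (-0.02, camera adjusted p = 0.409) did not pass.

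Wild-type replicate 3 held transcripts of the epididymal epithelium that the other wild-type libraries hardly had, with knockout replicate 3 next. Counts in wild-type replicates 1, 2 and 3 and knockout replicates 1, 2 and 3 were 3, 0, 484, 0, 2 and 54 for the protease inhibitor gene Spink8, 0, 0, 71, 1, 0 and 12 for the defensin gene Defb28, 7, 7, 92, 2, 6 and 12 for Ehf, and 10, 7, 161, 14, 20 and 40 for the keratin gene Krt19. No biological explanation was tested for this difference between libraries of the same genotype.

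The sex-linked germ cell list was higher as a group, with 24 of 29 members higher and a mean log2 fold change of 0.15 (camera adjusted p = 3.88e-06, and adjusted p = 0.27 with an estimated correlation). It joins the X-linked germ cell and Y-linked lists, which had already passed on the same data, so it restates them and is no separate support. The list also holds Y-linked genes, such as Usp9y and Eif2s3y, that were not listed for expression in germ cells. In the blocked edgeR fit adjusted over the list alone 10 members rose, with Zfy2, Tex11, Tktl1 and Usp26 among them. After a GC correction with the block the list kept a mean of 0.107 and passed under the preset correlation (camera adjusted p = 8.98e-05). The X-linked and Y-linked lists did not pass with the correction without the block. With the block and an estimated correlation the joint list did not pass even uncorrected (camera adjusted p = 0.168). A GC trend is thus not excluded. A larger share of early meiotic cells in the knockout testes could account for part of this rise, as autosomal early meiotic genes had a blocked mean of 0.109. The sex-linked excess of 0.043 had a permutation p over genes of 0.26. That p does not show that the lists rose equally, because genes are not independent replicates. In pair 1 the sex-linked list stood at 0.109 and the early meiotic list at -0.021. There the X-linked germ cell list stood at 0.038 and the Y-linked list at 0.268, the latter with Zfy1 (0.737) and Zfy2 (0.82). The counts of these 2 near-identical genes are uncertain, and 1 pair excludes nothing, so pair 1 does not decide on a larger share of early meiotic cells. With the axis list as a covariate the 9 sex-linked genes with a blocked edgeR adjusted p under 0.1 kept a median of 0.552 of 0.792, and Zfy2 had 0.83 ± 0.12 (edgeR adjusted p = 0.34), but these genes were picked for their size, so a share of early meiotic cells and a rise within cells cannot be told apart for them. An effect of genotype within cells stays open, as untested.

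Cholesterol synthesis genes were lower by a mean log2 fold change of -0.17 (camera adjusted p = 4.53e-10, and adjusted p = 0.841 with an estimated correlation). A GC trend as the whole cause is argued against by a mean of -0.163 after GC correction with the block (camera adjusted p = 6.04e-09). Without pair 3 the blocked mean was -0.047 and the list did not pass (camera adjusted p = 0.283), consistent with a difference that rests largely on 1 pair of libraries, in which the epididymis and rete list stood at -1.22 and the Leydig list at -0.64. Fewer Leydig cells cannot be told apart: with the Leydig list as a covariate the mean was -0.163, but that list differed by -0.04 between the groups, with pairs from -0.64 to 0.62, so the covariate could hardly move it. An effect of genotype beyond pair 3 did not pass in that test, and within pair 3 it stays open.

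Mitochondrially encoded RNAs were higher in 17 of 17 members, with a mean log2 fold change of 0.29 (camera adjusted p = 2.41e-21, adjusted p = 0.152 with an estimated correlation), and structured small RNAs such as Rmrp, Rpph1 and Rn7sk in 21 of 30, with 0.34 (camera adjusted p = 2.29e-07, adjusted p = 0.152 with an estimated correlation). Against a higher expression of the respiratory chain as a whole, 78 nuclear-encoded members had a mean of -0.028 (95% bootstrap interval over genes -0.044 to -0.013). That interval leaves out variation between mice, and the nuclear-encoded list did not pass as lower (camera adjusted p = 0.15, and 0.0947 with the block). Against a GC trend as the whole cause, the mitochondrial and structured lists both passed after GC correction with the block (0.216 and 0.354). Carry-over of ribosomal RNA, as from a difference in RNA selection between libraries, cannot be told apart from genotype, since in the only pair without a higher Gm42418 (-0.033, pair 2) the lists stood at 0.12 and 0.371, and 1 pair excludes nothing. The Gm42418 ratio was 0.776 in pair 1 and 0.428 in pair 3, where the mitochondrial list stood at 0.495 and 0.254 and the structured list at 0.129 and 0.529, so that over the pairs the mitochondrial list rose with Gm42418 and the structured list did not. An effect of genotype stays open, as untested.

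Other splits of the 6 libraries into 3 against 3 were tested for each count. Without the block the real split gave 0 genes, a count that all 10 splits reach whatever the data, so it tests nothing. The highest other count was 42, for wild-type replicate 1 with knockout replicates 1 and 2, and the cause of that count was not tested. In the real split edgeR had 374 genes at an unadjusted p under 0.05, and DESeq2 called 2 and voom 0. For lists, 7 of the 10 splits gave at least 8, the highest other being 16, so the count of passing lists was not particular to the real split. Of the 4 splits that part every pair, 1, the real one, gave 8 genes or more with the block (highest other 2), 2 gave 10 lists or more (highest other 11), and 1, the real one, gave 86 or more sex-linked genes higher at an unadjusted p under 0.05 (highest other 28). With 10 or 4 splits no share under 0.05 can be reached.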
